A study of Mus musculus with 16 samples.

How the data were processed

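Total RNA of mouse Hoxb8 macrophages was measured in 16 libraries of 4 groups, macrophages alone and macrophages after 45, 90 and 180 min with apoptotic human Jurkat cells. Per the labels' protocols, RNA was isolated with a column kit, depleted of ribosomal RNA and made into libraries with a directional (strand-marking) kit. The authors deposited 1 table of raw counts per gene for all libraries, with no normalization. Per the submitters' processing notes, the tools named are STAR 2.7.9a, SAMtools and HTSeq and the genome build is mm39, with no roles, settings or annotation release. The strand setting of the counting, the handling of reads shared between genes, and the handling of reads from the human cells are not given in the sources used here. Reads of human RNA that resemble mouse genes could therefore be among the counts, and genes with near-identical copies may gain or lose reads.

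The table's column names give the group of each library but no replicate number, so libraries were assigned to groups only, and numbers 1 to 4 within a group are names in file order. The table held 55416 Ensembl gene IDs, of which 25663 had at least 1 count, and no row without a gene. Symbols, gene classes, length and GC content came from the GENCODE M21 annotation, which is for the build before mm39, so no coordinates are printed. Symbols were found for 52083 IDs, and IDs with no symbol held 0.223% to 0.341% of counts per library. A noncoding gene was called intronic where it lay within a coding gene on the same strand and touched none of that gene's exons. Totals per library ranged from 10.7 M to 41.7 M counts. Replicates of a group differed from each other by more than sampling noise, with chi-square values per degree of freedom from 3.98 to 10.2 over all pairs, so each library was counted as 1 replicate.

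Genes were kept by edgeR's expression filter with a minimum count of 10 and a minimum total count of 15, which left 14168. Library sizes were scaled by the trimmed mean of M values. Each comparison used edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with all 16 libraries sharing 1 estimate of the spread, group as the only term, and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Log2 fold changes are the model's coefficients without shrinkage, and each standard error is the size of the coefficient divided by the square root of its F statistic. The 6 comparisons were each time against macrophages alone and each pair of times, and a test over the 3 times asked for any change. Values in CPM are counts divided by the scaled library size, except that those of markers of other cell types are counts summed over a group and divided by its summed, unscaled totals.

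Lists of genes were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternative settings set out in advance. They were 29 lists with 684 entries, of which 682 matched a gene of the table. They covered immediate early genes, inflammatory cytokines, NF-kB feedback, interferon response, resolution, apoptotic cell receptors, engulfment and actin, phagosome and lysosome, cholesterol efflux, cholesterol synthesis, glycolysis, solute carriers, chaperones, integrated stress response, polyamines, NRF2 targets, pausing and elongation factors, EGR targets, cell cycle, histones, mitochondrial and ribosomal protein genes. The rest were markers of macrophages, neutrophils, T or Jurkat cells, dendritic cells, progenitors, B cells, and erythroid or mast cells. Lists share members, so they are not independent tests. Each list with at least 5 tested members, 24 in all, was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 24 lists. Camera with an estimated correlation and fry were run beside it. Fry's first p-value tests whether the genes of a list move on balance one way and its mixed p-value whether they change in either direction, and neither compares the list with other genes.

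Genes named in the text were, for each time against macrophages alone, the 10 with the largest rise and the 10 with the largest fall among called genes with an average log2 CPM of at least 1 whose groups did not overlap, and 5 and 5 between times. Gene models with only clone or numbered names were passed over. Up to 4 members of each list with the smallest p in a comparison could be named as examples, as could 16 genes set in advance, among them Egr1, Egr2, Egr3, Fos, Nr4a1, Myc, Tnf, Il1b, Il10, Mertk, Abca1, Slc2a1, Slc16a1 and Odc1. Some genes that the rule would name are not reported here. Of the 16 set in advance, the text reports the calls of all as counts and the values of some.

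The overlap of calls between times was set beside 20 simulated data sets of unchanged groups against the same controls, beside the overlap of independent lists, and beside all 6 ordered splits of the 4 controls into 2 and 2. Alternatives planned in advance were DESeq2's scaling, DESeq2 1.42.0, limma with voom, no filter, a stricter filter of at least 1 CPM in 4 libraries, only the libraries compared, removal of mitochondrial genes, an absolute log2 fold change of at least 1, and leaving out each library in turn. Thinning to the smallest total, removal of a length and GC trend, and a test of coding genes alone were added after the data were seen. Length and GC content were known for 99.4% of tested genes. For each pair of groups all 35 splits of the 8 libraries into 4 and 4 were tested, and 100 random splits for the test over all times.

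The test was checked on counts simulated from the real means and library sizes, with 200 of 14168 genes changed. Each fold was given to 66 or 67 genes. The real data had 1529, 2986 and 4404 calls at the 3 times, so the simulated shares may not carry over to them. In the simulated 45 min comparison 70.1% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered, and 7.65% of calls were false. At 90 min the shares recovered were 67.2%, 74.6% and 98.5%, with 5.33% of calls false. At 180 min they were 61.2%, 76.1% and 90.9%, with 7.32% of calls false. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with Matplotlib 3.10.9.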

Results

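RNA was sequenced from mouse macrophages of the Hoxb8 line, which are grown from bone marrow progenitors held in an immature, dividing state by the transcription factor Hoxb8 until they are allowed to mature. The macrophages were kept alone or were given apoptotic Jurkat cells, a human T cell leukaemia line, for 45, 90 or 180 min. Uptake of dying cells by a phagocyte is called efferocytosis, and the series title places it beside the release of paused RNA polymerase. Each of the 4 groups held 4 libraries, 16 in all, made from total RNA depleted of ribosomal RNA. Counts per library summed to between 10.7 M and 41.7 M. The mean total was 24.7 ± 4.07 M (SD, n = 4) for macrophages alone, 31.7 ± 7.27 M at 45 min, 15.7 ± 1.97 M at 90 min and 17.9 ± 6.40 M at 180 min (n = 4 each). Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels also do not say when the macrophages kept alone were harvested, so time in culture and exposure to apoptotic cells cannot be told apart in any comparison with that group. They give no group kept alone for each time, so the comparisons between times have the same limit. Of 14168 genes tested, 6322 changed at some time by edgeR's quasi-likelihood test over the 3 times with Benjamini-Hochberg adjustment. The biological coefficient of variation was 7.81%.

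The comparison of 45 min with macrophages alone asks which transcripts had changed soonest after the apoptotic cells were added. At 45 min the largest rises were those of the early growth response factors, zinc-finger transcription factors that are switched on within minutes of many stimuli. Egr1 (ENSMUSG00000038418) went from 14.4 ± 1.98 counts scaled to library size (CPM; SD, n = 4) to 69.0 ± 7.2 CPM (n = 4). By edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted, this was a rise of 2.27 (SE 0.097, adjusted p = 5.98e-27) on the log2 scale. Egr3 rose by 4.39 (SE 0.36), from 0.217 ± 0.179 CPM, and Egr2 by 2.39 (SE 0.21). The other 7 of the 10 largest rises included Nr4a1, a nuclear receptor gene (1.38, SE 0.18), Edn1, which encodes the vasoconstrictor endothelin (1.34, SE 0.21), and Cxcl2, a chemokine that attracts neutrophils (1.28, SE 0.057). Fosb, a subunit of the AP-1 transcription factor, rose by 1.24, the sarcomere protein gene Mybpc3 by 1.24, Ier2 by 1.11 and the anti-inflammatory cytokine Il10 by 1.10. Here and below, the largest rises and falls are those among genes that met the rule for naming. At 45 min 208 genes fell at least 2-fold, most of which did not meet it. Among those that did, the 10 largest falls ranged from -0.66 for Ahnak, which encodes a giant scaffold protein, to -1.19 for Kcnq1ot1, an imprinted antisense RNA. Between them lay the imprinted antisense RNA Airn (-0.82), the splicing regulator Rbm4 (-0.95), the inositol transporter Slc5a3 (-0.78) and the histone gene Hist1h2bb (-0.81). The other 4 were Klhl42, Igip, Xndc1 and Abhd18. Il10 was not called without library 1 of 45 min (0.83, adjusted p = 0.144, and 0.00114 to 0.144 over all alternatives), nor Igip without library 4 of 45 min (-0.69, adjusted p = 0.0878, and 0.00183 to 0.0878). Nor was Xndc1 called without library 2 or 4 of macrophages alone (-0.90 and -0.82), Abhd18 without 1, 2 or 4 of macrophages alone or 1, 3 or 4 of 45 min (-0.67 to -0.57), or Hist1h2bb without any 1 of macrophages alone or 1 or 2 of 45 min (-0.88 to -0.67). Over all alternatives the adjusted p ran from 0.00794 to 0.0757 for Xndc1, 0.01 to 0.176 for Abhd18 and 0.015 to 0.177 for Hist1h2bb. The calls of these 3 were also lost with libraries thinned to the smallest total (-1.01, -0.53 and -0.96). Those of Abhd18 and Hist1h2bb were lost with no filter (-0.66 and -0.80), and that of Abhd18 with a trend on gene length and GC content removed (-0.53).

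In total 664 genes rose and 865 fell at 45 min, 15 and 208 of them at least 2-fold. Among protein-coding genes the split was 638 higher and 605 lower, and 11 in each direction changed at least 2-fold. Of 1004 noncoding genes that lie inside an intron of a coding gene on the same strand 213 fell, 175 of them at least 2-fold, and 4 rose, with a median log2 fold change of -0.71 against 0.02 for coding genes. They took 0.197 ± 0.0164% of counts in macrophages alone and 0.135 ± 0.0143% at 45 min (SD, n = 4 each). The 4 libraries at 45 min lay entirely above or below the 4 of macrophages alone for 2401 genes, 16.9% of those tested, where chance gives 2.86%. With a trend on gene length and GC content removed from each library, an alternative chosen after the data were seen, 893 genes were called in place of 1529. Antisense and overlapping genes such as Kcnq1ot1 and Airn are uncertain because the sources do not state that counting used strand, and histone genes can share reads with near-identical copies.

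Gene lists fixed before the data were examined were tested with camera, which compares the members of a list with the other genes. At 45 min 16 of 24 were called, 15 up and 1 down. The other genes included the intronic noncoding ones, whose median was -0.71 against 0.02 for coding genes. List tests were not run on coding genes alone, so the part of the intronic genes in these calls was not tested. Other splits of the same 8 libraries into 4 and 4 called up to 15 lists. Counts of members are over all genes tested, and the count in parentheses after each is the one adjusted over the list alone. Of 35 measured immediate early genes, which respond to a stimulus without new protein synthesis, 27 (28) rose, with a median of 0.51. The camera adjusted p = 7.32e-37, and adjusted p = 9.19e-06 with an estimated correlation. Rises included Dusp1, a phosphatase that turns off MAP kinases (0.68, SE 0.044), the AP-1 subunit Fos (0.68, SE 0.050), Csrnp1 (0.77, SE 0.058) and the growth regulator Myc (0.61, SE 0.10). Of 21 inflammatory cytokine and chemokine genes 11 (11) rose (adjusted p = 1.86e-13, and adjusted p = 0.00252 with an estimated correlation). Among these were the chemokines Ccl4 (0.72) and Ccl3 (0.66) and the cytokines Tnf (0.57) and Il1b (0.45). Without library 4 of macrophages alone Il1b was not called (0.39, adjusted p = 0.0559, and 0.000964 to 0.0559 over all alternatives). Of 12 regulators and targets of the EGR factors 8 (8) rose (adjusted p = 1.07e-12, and adjusted p = 0.00224 with an estimated correlation), and Egr1, Egr2 and Egr3 count in this list and in the immediate early one. Of 17 feedback genes of NF-kB, a transcription factor of inflammation, 5 (5) rose (adjusted p = 1.59e-05, and adjusted p = 0.0309 with an estimated correlation), with the deubiquitinase gene Tnfaip3 at 0.36 and Nfkbid at 0.62.

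The other 12 lists called at 45 min were not called with an estimated correlation. Of 40 ribosomal protein genes, which can share reads with their many pseudogenes, 23 (30) rose, for example Rplp0 by 0.26 (SE 0.046) (list median 0.18, adjusted p = 8.16e-14, and adjusted p = 0.0848 with an estimated correlation). The mitochondrial list held 15 genes, of which 9 passed the expression filter, and why the others did not was not tested. Of the 9 tested, 8 (9) fell, with the ribosomal RNA mt-Rnr2 at -0.34 (list median -0.31, adjusted p = 8.4e-05, and adjusted p = 0.147 with an estimated correlation). Mitochondrial genes took 4.45 ± 0.223% of counts in macrophages alone and 3.54 ± 0.178% at 45 min (SD, n = 4 each). Interferon response genes rose in 10 (13) of 29 cases (adjusted p = 8.4e-05), macrophage identity markers in 6 (12) of 16 (adjusted p = 2.06e-06) and genes of glycolysis and of glucose or lactate transport in 7 (8), with 0 (1) lower, of 21 (adjusted p = 0.000133). Each of these 3 lists had adjusted p = 0.147 with an estimated correlation. Examples were the interferon-induced kinase Cmpk2 (0.17), the endotoxin co-receptor Cd14 (0.39) and the glucose transporter Slc2a1 (0.23). Of 18 integrated stress response genes 5 (8) rose (adjusted p = 0.000303), with Chac1, which degrades glutathione, at 0.73. Of 14 anti-inflammatory and resolution genes 4 (4) rose (adjusted p = 0.0107). Of 13 polyamine genes 3 (3) rose (adjusted p = 0.021), led by Odc1, the rate-limiting enzyme of polyamine synthesis, at 0.66. The last 3 lists all had adjusted p = 0.076 with an estimated correlation.

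Engulfment and actin regulators rose in 8 (10) and fell in 1 (2) of 41 cases at 45 min (adjusted p = 0.021), with the actin-binding protein Coro1a at 0.38. Phagosome and lysosome genes rose in 4 (9) and fell in 1 (1) of 43 (adjusted p = 0.0109), and both lists had adjusted p = 0.281 with an estimated correlation. NRF2 targets rose in 4 (4) of 16 cases (adjusted p = 0.021, and adjusted p = 0.276 with an estimated correlation). Cholesterol synthesis genes rose in 1 (1) of 23 (adjusted p = 0.0462, and adjusted p = 0.109 with an estimated correlation), that gene being Sqle at 0.32. The cholesterol synthesis call was lost without library 1 of macrophages alone (adjusted p = 0.129), 1, 3 or 4 of 45 min (0.0536, 0.0668 and 0.0783) or 2 or 4 of 180 min (0.052 and 0.0588), and its range over all alternatives was 0.00816 to 0.129. The NRF2 call was lost with the length and GC trend removed (adjusted p = 0.299, with a range of 0.00163 to 0.299). The other 8 lists were not called. Receptors for apoptotic cells and their bridging molecules rose in 5 (6) and fell in 2 (2) of 30 cases (adjusted p = 0.155), and the scavenger receptor Lrp1 fell by 0.33 (SE 0.050). Factors of polymerase pausing and elongation rose in 1 (1) and fell in 5 (6) of 32 (adjusted p = 0.114), with Cdk9, the kinase of the pause-release complex, at 0.20 and Polr2a, the largest subunit of RNA polymerase II, at -0.28. Cholesterol efflux genes rose in 3 (4) and fell in 2 (2) of 19 (adjusted p = 0.275), and the efflux pump Abca1 fell by 0.30 (SE 0.039). Solute carriers rose in 1 (1) and fell in 1 (1) of 15 (adjusted p = 0.701), cell cycle genes rose in 1 (1) of 30 (adjusted p = 0.103) and histone genes fell in 1 (0) of 42 (adjusted p = 0.174). The 5 neutrophil markers (adjusted p = 0.38) and 17 heat shock genes (adjusted p = 0.906) were also not called, and for heat shock genes median, mean and test differed in sign. Of 16 genes named before the data were examined, 11 rose, 1 fell and 4 were not called by edgeR at 45 min. Those not called included the apoptotic cell receptor Mertk at -0.11 (adjusted p = 0.181) and the lactate transporter Slc16a1 at 0.20 (adjusted p = 0.201).

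**Figure D1:**
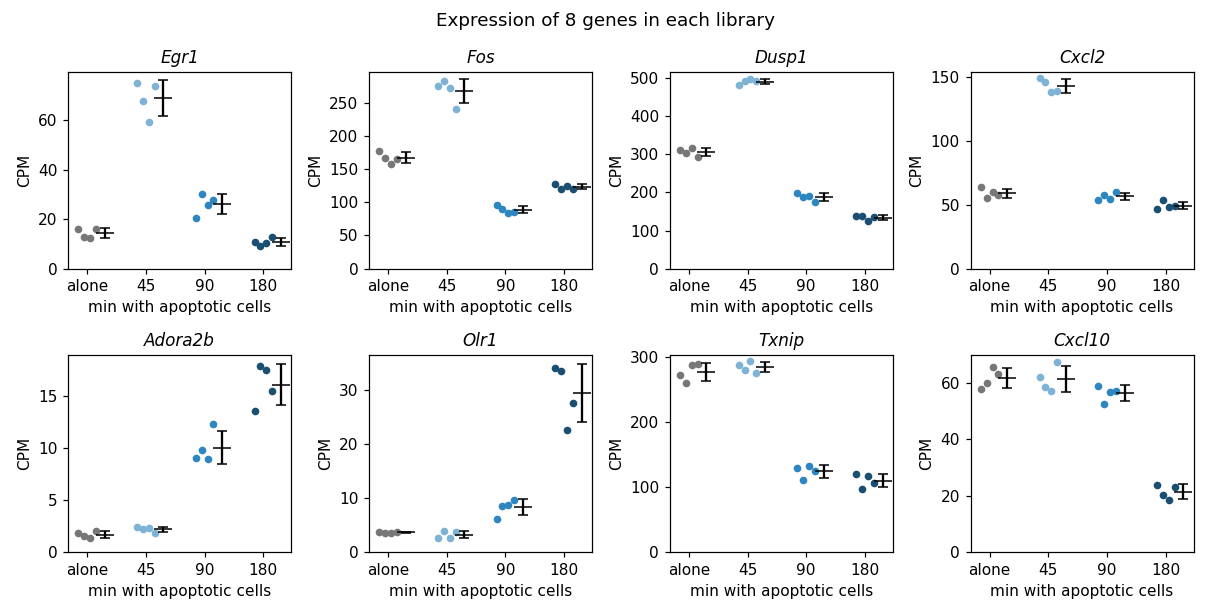
Expression of 8 genes in CPM (vertical axis) by minutes with apoptotic cells (horizontal axis), where each point is 1 of 4 libraries of a group and the dash and bars beside them show the mean and SD. Egr1, Fos, Dusp1 and Cxcl2 were highest at 45 min, Adora2b and Olr1 at 180 min, and Cxcl10 was lowest at 180 min.

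The comparison of 90 min with macrophages alone asks what had changed once exposure had gone on longer. After Egr3 (4.53, SE 0.37) and Egr2 (2.65, SE 0.21) the largest rise was that of Adora2b (ENSMUSG00000018500), a receptor for extracellular adenosine. Adora2b went from 1.67 ± 0.326 CPM alone to 10 ± 1.6 CPM at 90 min (SD, n = 4), a rise of 2.60 (SE 0.18, adjusted p = 2.39e-18) by edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted. Rapgef3, a Rap exchange factor switched on by cyclic AMP, rose by 1.55 (SE 0.18) and Cish, a cytokine-induced inhibitor of STAT signalling, by 1.63 (SE 0.11). The growth factor Mdk rose by 1.80 (SE 0.26), the ubiquitin ligase Trim17 by 1.65 (SE 0.21), and Mybpc3, Fhad1 and the mitochondrial transfer RNA mt-Tw by 2.17, 1.63 and 1.60. Txnip (ENSMUSG00000038393), an inhibitor of thioredoxin and of glucose uptake, fell by 1.16 (SE 0.053, adjusted p = 1.04e-25) in the same test. Btg2, an antiproliferative early gene, fell by 1.52 (SE 0.092). Fos, which had risen at 45 min, fell by 0.91 (SE 0.052). Others among the 10 largest falls were those of Pgap1, Fam43a, Amot, the kinase Nuak1, the aldolase Aldoc and the ephrin Efnb1, from -0.90 to -1.10. Aldoc was not called without library 3 of macrophages alone (-0.88, adjusted p = 0.0603, and 0.00728 to 0.0603 over all alternatives), and Efnb1 was not called with libraries thinned (-0.75, 0.00533 to 0.0647).

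In total 1573 genes rose and 1413 fell at 90 min, 303 and 33 of them at least 2-fold. Of those at least 2-fold, 129 and 16 were coding. Coding genes numbered 1251 of those that rose and 1373 of those that fell, and 1403 and 1230 in a test of coding genes alone, added after the data were seen. Long intergenic, antisense and processed noncoding transcripts had medians of 0.44, 0.42 and 0.44 against -0.02 for coding genes. The groups did not overlap for 3003 genes, 21.2% of those tested, where chance gives 2.86%.

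At 90 min 17 of 24 lists were called, 7 up and 10 down, and with an estimated correlation only the EGR list was still called. Other splits of the same libraries called up to 16. Of 12 EGR regulators and targets 9 (9) rose, in parentheses adjusted over the list alone, with a median of 0.58. The camera adjusted p = 3.01e-08, and adjusted p = 0.0217 with an estimated correlation. They included the EGR co-repressor Nab2 (1.29, SE 0.11) and the helix-loop-helix inhibitor Id2 (0.86, SE 0.045). Of 35 immediate early genes 20 (21) were higher and 8 (8) lower (adjusted p = 0.000985), with Myc at 1.28 and Dusp1 at -0.70. Inflammatory genes rose in 10 (10) and fell in 2 (2) of 21 cases (adjusted p = 0.000985), with the monocyte chemokines Ccl7 (0.72) and Ccl2 (0.51) and Tnf (0.75) higher and the chemokine Ccl5 (-0.34) lower. NF-kB feedback genes rose in 9 (9) and fell in 1 (2) of 17 (adjusted p = 0.00169). Anti-inflammatory genes rose in 8 (9) of 14 (adjusted p = 0.00391) and polyamine genes in 5 (6), with 0 (1) lower, of 13 (adjusted p = 0.0321), with the growth factor Pdgfb at 0.99 and Odc1 at 0.75. All 9 (9) tested genes of the mitochondrial list rose (adjusted p = 3.51e-07), mt-Cytb by 0.69 (SE 0.071), and the share of counts of all mitochondrial genes was 5.88 ± 0.546% (SD, n = 4). Each of these 6 lists other than EGR had adjusted p = 0.1 with an estimated correlation. The polyamine call was lost without library 2 of macrophages alone (adjusted p = 0.0503) or 3 of 90 min (0.0562), with a range over all alternatives of 1.56e-06 to 0.1.

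Integrated stress response genes fell in 12 (12) and rose in 3 (3) of 18 cases at 90 min (adjusted p = 0.000985, and adjusted p = 0.1 with an estimated correlation). The stress sensor Sesn2 fell by 0.53 (SE 0.078) and Atf4, the transcription factor at the centre of this response, fell by 0.25 (SE 0.043), while Cebpb rose by 0.67 (SE 0.049). Ddit4, an inhibitor of mTORC1, fell by 2.02 (SE 0.40). That gene was not among the 10 largest falls because it missed the rule's limit on average level or on overlap of the groups. Phagosome and lysosome genes fell in 14 (17) and rose in 2 (2) of 43 (adjusted p = 0.000363, and adjusted p = 0.199 with an estimated correlation), with the protease Ctsd at -0.26. Engulfment and actin regulators fell in 12 (13) and rose in 2 (2) of 41 (adjusted p = 0.00327), with Tln1, which links integrins to actin, at -0.30. NRF2 targets fell in 7 (7) and rose in 1 (1) of 16 (adjusted p = 0.00717), the gene that rose being the cystine transporter Slc7a11 at 0.70. The last 2 lists had adjusted p = 0.257 with an estimated correlation. Cholesterol efflux genes fell in 9 (9) and rose in 3 (3) of 19 (adjusted p = 0.0211, and adjusted p = 0.264 with an estimated correlation), including the lipoprotein gene Apoe at -0.42 and Abca1 at -0.15. Pausing and elongation factors fell in 9 (9) and rose in 3 (3) of 32 (adjusted p = 0.0211, and adjusted p = 0.178 with an estimated correlation), with Polr2a at -0.47. Interferon genes fell in 11 (13) and rose in 1 (1) of 29 (adjusted p = 0.00327), the gene that rose being Oas2 (0.53), and heat shock genes fell in 3 (3) of 17 (adjusted p = 0.0336). These 2 lists had adjusted p = 0.262 with an estimated correlation. The heat shock call was lost without library 3 of macrophages alone (adjusted p = 0.0651) or 2 of 90 min (0.0663) and with libraries thinned (0.062), with a range over all alternatives of 0.00741 to 0.262. The efflux call was lost without library 4 of 90 min (adjusted p = 0.05, range 0.00684 to 0.264) and the pausing call with the length and GC trend removed (adjusted p = 0.0597, range 0.00128 to 0.178).

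Glycolysis and transport genes fell in 12 (12) and rose in 4 (4) of 21 cases at 90 min (adjusted p = 0.0436, and adjusted p = 0.478 with an estimated correlation). The hexokinase Hk2 fell by 0.39 (SE 0.061), while Pfkfb3, which makes an activator of glycolysis, rose by 0.39 (SE 0.044) and Slc2a1 by 0.22 (SE 0.053). The glycolysis call was lost without library 1 or 3 of macrophages alone (adjusted p = 0.0663 and 0.127), 3 or 4 of 90 min (0.0575 and 0.0976) or 2 of 180 min (0.0504), with libraries thinned, with the length and GC trend removed and by fry (0.0803, 0.0597 and 0.128), with a range of 0.0262 to 0.478. Ribosomal protein genes fell in 11 (14) and rose in 3 (4) of 40 (adjusted p = 0.00946, and adjusted p = 0.512 with an estimated correlation). The other 7 lists were not called. Among receptors and bridging molecules for apoptotic cells 6 (6) of 30 rose and 4 (6) fell (adjusted p = 0.928). The scavenger receptors Olr1 (1.20, SE 0.16) and Stab1 (0.64, SE 0.052) and the lipid receptor Cd300lf (0.72, SE 0.048) rose, and Mertk fell by 0.29 (SE 0.054). Solute carriers had 3 (3) higher and 3 (3) lower of 15 (adjusted p = 0.928), cholesterol synthesis genes 2 (2) and 2 (2) of 23 (adjusted p = 0.821) and cell cycle genes 1 (0) and 1 (0) of 30 (adjusted p = 0.382). Histone genes had 4 (4) higher and 3 (3) lower of 42 (adjusted p = 0.928), macrophage identity markers 1 (1) and 5 (6) of 16 (adjusted p = 0.0741), and neutrophil markers 1 (1) lower of 5 (adjusted p = 0.589). Median, mean and test differed in sign for the receptor, solute carrier and histone lists. Of the 16 genes named in advance, 10 rose, 3 fell and 3 were not called by edgeR at 90 min.

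The comparison of 180 min with macrophages alone asks what had changed by the latest time measured. Adora2b reached 16.1 ± 2.0 CPM (SD, n = 4). Olr1 (ENSMUSG00000030162), a receptor for oxidised lipoproteins and apoptotic cells, went from 3.62 ± 0.0975 to 29.5 ± 5.42 CPM (n = 4 each). These were rises of 3.28 (SE 0.17, adjusted p = 1.11e-23) and 3.02 (SE 0.15, adjusted p = 3.03e-25) by edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted. Egr3 was still higher by 3.38 (SE 0.39). The other 7 of the 10 largest rises included the kinase adaptor Cables1 (2.61, SE 0.31), Spsb1, an adaptor of a ubiquitin ligase (2.59, SE 0.15), Rapgef3 (2.43, SE 0.17) and Smad6, an inhibitor of BMP signalling (2.30, SE 0.22). The growth factor Pdgfa rose by 2.01, Mir17hg, the host transcript of a microRNA cluster, by 1.99 and Cish by 1.96. Cxcl10 (ENSMUSG00000034855), a chemokine induced by interferon, fell by 1.53 (SE 0.076, adjusted p = 4.83e-25) in the same test, from 61.8 ± 3.47 to 21.4 ± 2.59 CPM. Other falls were those of Iigp1, an interferon-induced GTPase (-1.35, SE 0.048), the integrin Itga4 (-1.37, SE 0.079), Txnip (-1.33, SE 0.054), Btg2 (-1.28, SE 0.089), Chac1 (-1.57, SE 0.21) and the lipase Lipg (-1.68, SE 0.28). The last 3 of the 10 largest falls were those of Psme2b (-1.39), which can share reads with its near-identical parent gene, the mitochondrial phosphatase Ppm1k (-1.35) and Zfp467 (-1.31).

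In total 2139 genes rose and 2265 fell at 180 min, 397 and 105 of them at least 2-fold. Of those at least 2-fold, 216 and 60 were coding. Coding genes made up 1794 of those that rose and 2165 of those that fell, and 2074 and 1956 in a test of coding genes alone. The groups did not overlap for 4050 genes, 28.6% of those tested, where chance gives 2.86%.

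At 180 min 8 of 24 lists were called, 4 up and 4 down, and interferon response genes had the lowest camera p. Other splits of the same libraries called up to 10. Of 29 measured, 27 (27) fell, in parentheses adjusted over the list alone (where 1 also rose), with a median of -0.56 and adjusted p = 1.73e-26. This list alone was also called with an estimated correlation, at adjusted p = 0.00555 with an estimated correlation. Cmpk2, a nucleotide kinase, stood at -1.0, the antiviral genes Ifit3b and Ifit1 at -0.99 and -0.89, and the antiviral GTPase Mx1 at -0.98. All 9 (9) tested genes of the mitochondrial list rose (median 0.91, adjusted p = 1.4e-08), mt-Cytb by 1.14 (SE 0.071), and all mitochondrial genes took 7.0 ± 0.611% of counts (SD, n = 4). NF-kB feedback genes rose in 9 (11) and fell in 1 (1) of 17 cases (adjusted p = 0.000843), with Nfkbid at 1.43 and Nfkbiz at -0.93. Anti-inflammatory genes rose in 6 (7) of 14 (adjusted p = 0.0138), including Pdgfb (1.55) and the haem-degrading enzyme Hmox1 (0.59). Each of the last 3 lists had adjusted p = 0.112 with an estimated correlation. EGR regulators and targets rose in 7 (7) and fell in 3 (3) of 12 (adjusted p = 0.00428, and adjusted p = 0.128 with an estimated correlation). Nab2 rose by 1.54 (SE 0.11) and Id2 by 1.14 (SE 0.045), while Egr1 was below its level in macrophages alone (-0.39, SE 0.11). Integrated stress response genes fell in 9 (9) and rose in 2 (2) of 18 (adjusted p = 0.00583, and adjusted p = 0.135 with an estimated correlation), with Sesn2 at -1.11 and Atf4 at -0.41.

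Phagosome and lysosome genes fell in 22 (23) and rose in 4 (5) of 43 cases at 180 min (adjusted p = 0.00428, and adjusted p = 0.366 with an estimated correlation). Rubcn, a regulator of phagocytosis linked to autophagy proteins, fell by 0.57 (SE 0.065) and the transcription factor Mitf fell by 0.41 (SE 0.047). Engulfment and actin regulators fell in 14 (18) and rose in 5 (5) of 41 (adjusted p = 0.0287, and adjusted p = 0.422 with an estimated correlation), with Tln1 at -0.41. This call was lost without library 3 of macrophages alone (adjusted p = 0.0675) and with libraries thinned (0.0521), with a range over all alternatives of 0.00171 to 0.422. The other 16 lists were not called. Receptors and bridging molecules rose in 10 (10) and fell in 7 (8) of 30 (adjusted p = 0.594), with Stab1 higher by 1.07 (SE 0.052), Cd300lf by 0.76 (SE 0.048) and the receptor kinase Axl lower at -0.62 (SE 0.088). Immediate early genes had 16 (17) higher and 10 (10) lower of 35 (adjusted p = 0.0981), with the GTPase Rhob at 0.94 and the MAP kinase phosphatases Dusp1 and Dusp6 at -1.20 and -1.03. Inflammatory genes had 6 (6) higher and 6 (6) lower of 21 (adjusted p = 0.873), with Tnf at 0.98 and Ccl5 at -0.61. Solute carriers had 4 (4) higher and 3 (3) lower of 15 (adjusted p = 0.844), with Slc7a11 at 1.34 and the arginine transporter Slc7a2 at 1.5. NRF2 targets, which share Slc7a11, had 6 (6) higher and 3 (5) lower of 16 (adjusted p = 0.262).

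Cholesterol efflux genes at 180 min had 5 (5) higher and 6 (6) lower of 19 (adjusted p = 0.763), and the lipid-sensing receptor Ppard rose by 1.28 (SE 0.092) while Pparg fell by 0.38 (SE 0.074). Glycolysis and transport genes had 4 (4) higher and 11 (12) lower of 21 (adjusted p = 0.227), with the kinase Sgk1 at 1.46 and Slc2a1 at 0.41. Polyamine genes had 6 (6) higher and 1 (1) lower of 13 (adjusted p = 0.0539), with Odc1 at 0.91. Macrophage identity markers had 2 (2) higher and 9 (9) lower of 16 (adjusted p = 0.0811), and the myeloid transcription factor Cebpa rose by 1.03 (SE 0.079). Pausing and elongation factors had 7 (7) higher and 9 (9) lower of 32 (adjusted p = 0.111), with Polr2a at -0.67. Cholesterol synthesis genes had 3 (3) higher and 1 (0) lower of 23 (adjusted p = 0.763), cell cycle genes 2 (1) and 1 (1) of 30 (adjusted p = 0.707), histone genes 1 (1) and 8 (8) of 42 (adjusted p = 0.129) and ribosomal protein genes 5 (5) and 7 (7) of 40 (adjusted p = 0.262). Heat shock genes fell in 4 (3) of 17 (adjusted p = 0.227) and neutrophil markers in 2 (2) of 5 (adjusted p = 0.388). Median, mean and test differed in sign for receptors, solute carriers and both cholesterol lists. Of the 16 genes named in advance, 9 rose, 4 fell and 3 were not called by edgeR at 180 min.

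**Figure D2:**
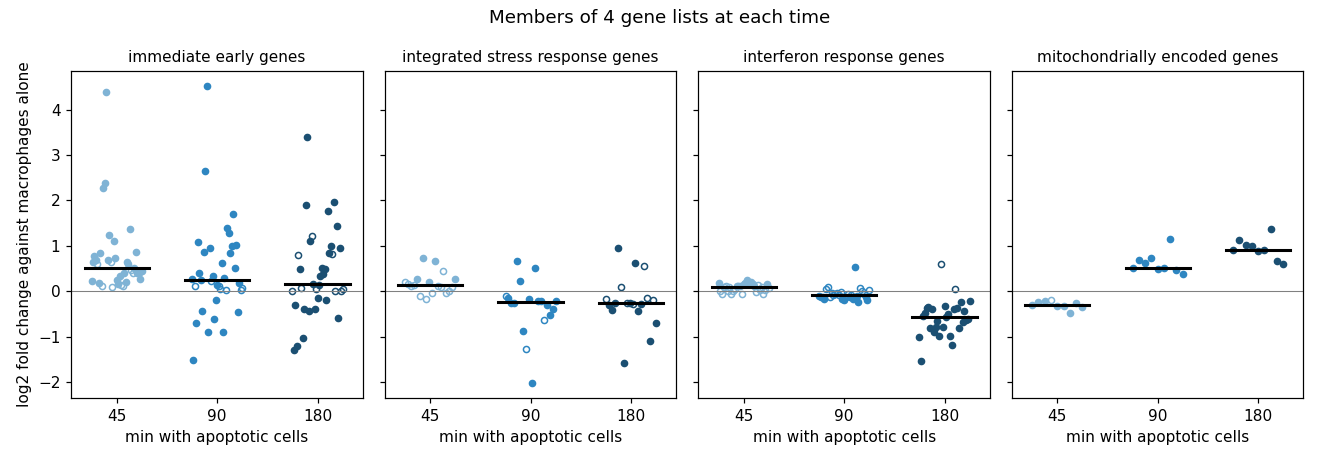
Log2 fold change against macrophages alone (vertical axis) of each measured member of 4 gene lists at 45, 90 and 180 min, where each point is a gene, filled where its adjusted p was under 0.05 and open where it was not, and the black line is the list median. The median of interferon response genes was -0.56 at 180 min, and that of mitochondrial genes went from -0.31 at 45 min to 0.91 at 180 min.

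The 90 min and 45 min groups were compared to see which changes came after the earliest time. Macrophages kept alone did not enter this difference, but they entered the filter, the scaling and the shared estimate of the spread. Early genes fell from 45 to 90 min, among them Btg2 (-2.15, SE 0.091), Ier2 (-1.71, SE 0.10), Fos (-1.59, SE 0.052), Egr1 (-1.40, SE 0.094), Dusp1 (-1.38, SE 0.045) and Cxcl2 (-1.34, SE 0.058). Over the same interval Adora2b rose by 2.22 (SE 0.17), Cables1 by 1.72 (SE 0.32), Fhad1 by 1.71 (SE 0.27), Cish by 1.66 (SE 0.10) and the linker histone gene Hist1h1d by 1.65 (SE 0.18). In total 2096 genes rose and 1888 fell, 487 and 32 of them at least 2-fold. Of those at least 2-fold, 111 and 26 were coding, and 225 and 2 were intronic noncoding genes. Coding genes were 1478 of the rises and 1869 of the falls, and 1696 and 1651 in a test of coding genes alone, while 296 of the 1004 intronic noncoding genes rose and 5 fell. The groups did not overlap for 3559 genes, 25.1% of those tested (chance 2.86%). Of 12 lists called, 1 up and 11 down, 2 were also called with an estimated correlation, and other splits of the same libraries called up to 13. Camera set these lists against genes that included the intronic noncoding ones, with a median of 0.79 against -0.02 for coding genes. The part of the intronic genes in the list calls was not tested. Immediate early genes fell in 18 (18) and rose in 6 (6) of 35 cases, in parentheses adjusted over the list alone (adjusted p = 3.77e-06). Integrated stress response genes fell in 13 (14) and rose in 2 (2) of 18 (adjusted p = 4.19e-07), with Chac1 at -1.59, and both lists had adjusted p = 0.0341 with an estimated correlation.

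All 9 (9) tested genes of the mitochondrial list rose from 45 to 90 min (adjusted p = 1e-09). Ribosomal protein genes fell in 33 (35) of 40 cases (adjusted p = 8.49e-13), interferon genes in 16 (19), with 1 (1) higher, of 29 (adjusted p = 4.19e-07), and phagosome and lysosome genes in 23 (24), with 1 (2) higher, of 43 (adjusted p = 4.19e-07). Actin regulators fell in 22 (25) and rose in 2 (3) of 41 (adjusted p = 8.04e-06), NRF2 targets in 9 (12), with 1 (1) higher, of 16 (adjusted p = 2.85e-05) and cell cycle genes in 2 (1) of 30 (adjusted p = 0.0447). These 7 lists had adjusted p = 0.0853 with an estimated correlation. Macrophage identity markers fell in 12 (13) of 16 (adjusted p = 8.69e-07, and adjusted p = 0.167 with an estimated correlation), glycolysis genes in 14 (14), with 3 (3) higher, of 21 (adjusted p = 7.05e-05, and adjusted p = 0.17 with an estimated correlation) and cholesterol efflux genes in 9 (9), with 3 (3) higher, of 19 (adjusted p = 0.0146, and adjusted p = 0.249 with an estimated correlation). The cell cycle call was lost without library 2 or 4 of macrophages alone (adjusted p = 0.0501 and 0.051), 1 or 3 of 45 min (0.0527 and 0.0755), 1 of 90 min (0.109) or 1, 3 or 4 of 180 min (0.0557, 0.0502 and 0.0513) and with libraries thinned (0.0914), with a range of 0.00097 to 0.109. The efflux call was lost with the length and GC trend removed (adjusted p = 0.0789, range 0.00143 to 0.249). Median, mean and test differed in sign for the receptor, solute carrier, polyamine and EGR lists, which were not called.

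The 180 min and 90 min groups were compared for changes that came last. Interferon response genes fell in 28 (28) of 29 cases, in parentheses adjusted over the list alone (where 1 also rose), with a median of -0.45 (adjusted p = 1.91e-42, and adjusted p = 0.000632 with an estimated correlation). Cxcl10 fell by 1.40 (SE 0.077), Cmpk2 fell by 0.90 (SE 0.038) and Ifit1 fell by 0.81 (SE 0.037). Olr1 rose by 1.82 (SE 0.14), Cables1 by 1.43 (SE 0.29), Spsb1 by 1.38 (SE 0.15), the transcription factor Klf2 by 1.26 (SE 0.14) and Nuak1 by 1.21 (SE 0.15). Egr1 fell by 1.26 (SE 0.11), and the other 3 of the 5 largest falls were those of Mir221 (-1.48), Dand5 (-1.19) and Hist2h3c2 (-1.18). Dand5 was not called without library 3 of 90 min (-0.88, adjusted p = 0.116, and 0.0044 to 0.116 over all alternatives). In total 631 genes rose and 987 fell, of which 605 and 906 were coding, and the groups did not overlap for 1738 genes, 12.3% of those tested (chance 2.86%). Of the 6 lists called, 3 up and 3 down, the interferon list alone was also called with an estimated correlation, and other splits of the same libraries called up to 7. NRF2 targets rose in 8 (9) and fell in 0 (1) of 16 cases (adjusted p = 3.23e-06), with Hmox1 at 0.65. Inflammatory genes fell in 11 (12) and rose in 2 (2) of 21 (adjusted p = 0.000209), with Ccl4 at -0.88, and both lists had adjusted p = 0.153 with an estimated correlation. Mitochondrial genes rose in 8 (8) of 9 (adjusted p = 0.00012) and histone genes fell in 7 (8) and rose in 1 (1) of 42 (adjusted p = 0.039), both with adjusted p = 0.336 with an estimated correlation. Cholesterol efflux genes rose in 4 (4) and fell in 1 (1) of 19 (adjusted p = 0.0381, and adjusted p = 0.489 with an estimated correlation). The efflux call was lost without library 1 or 4 of 90 min (adjusted p = 0.0772 and 0.0727) or 1 of 180 min (0.119) and with the length and GC trend removed (0.123), with a range over all alternatives of 0.00944 to 0.489. The histone call was lost without library 1 or 4 of 90 min (adjusted p = 0.0682 and 0.0523) or 3 of 180 min (0.101), with a range of 0.00644 to 0.336. Median, mean and test differed in sign for 7 lists that were not called, those of anti-inflammatory, actin, phagosome, solute carrier, stress response, pausing and macrophage identity genes.

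The 180 min and 45 min groups span the widest interval with apoptotic cells present, and 2596 genes rose and 2556 fell between them, the most of the 6 comparisons, with 671 and 94 at least 2-fold. Of those at least 2-fold, 203 and 75 were coding, and 308 and 3 were intronic noncoding genes. Coding genes were 1905 of the rises and 2490 of the falls, and 2172 and 2212 in a test of coding genes alone, and 380 of 1004 intronic noncoding genes rose and 13 fell. The groups did not overlap for 4578 genes, 32.3% of those tested (chance 2.86%). The 5 largest rises were those of Olr1 (3.19, SE 0.15), Cables1 (3.14, SE 0.31), Adora2b (2.90, SE 0.16), Spsb1 (2.52, SE 0.15) and Smad6 (2.49, SE 0.22). The 5 largest falls were those of Egr1 (-2.66, SE 0.10), Chac1 (-2.30, SE 0.21), Btg2 (-1.92, SE 0.088), Dusp1 (-1.88, SE 0.046) and Edn1 (-1.83, SE 0.23). Intronic noncoding genes had a median of 0.90 against -0.02 for coding genes, and their part in the list calls was not tested. Of 10 lists called, 1 up and 9 down, the interferon list alone was also called with an estimated correlation, and other splits of the same libraries called up to 12. Its genes fell in 27 (27) of 29 cases, in parentheses adjusted over the list alone (adjusted p = 6.88e-28, and adjusted p = 0.00443 with an estimated correlation). All 9 (9) tested genes of the mitochondrial list rose (adjusted p = 5.3e-10), immediate early genes fell in 18 (19) and rose in 7 (8) of 35 (adjusted p = 9.44e-05) and stress response genes fell in 11 (11) and rose in 2 (2) of 18 (adjusted p = 9.29e-05). Each of these 3 had adjusted p = 0.0706 with an estimated correlation. Phagosome genes fell in 26 (26) and rose in 4 (5) of 43 (adjusted p = 1.82e-05) and actin regulators in 25 (25), with 3 (6) higher, of 41 (adjusted p = 0.000209), both with adjusted p = 0.211 with an estimated correlation. Ribosomal protein genes fell in 29 (32) and rose in 1 (2) of 40 (adjusted p = 2.99e-07) and macrophage identity markers in 14 (14), with 1 (1) higher, of 16 (adjusted p = 1.82e-05), both with adjusted p = 0.277 with an estimated correlation. Inflammatory genes fell in 10 (11) and rose in 3 (3) of 21 (adjusted p = 0.000328, and adjusted p = 0.132 with an estimated correlation), and glycolysis genes fell in 13 (15) and rose in 3 (3) of 21 (adjusted p = 0.00374, and adjusted p = 0.34 with an estimated correlation). Median, mean and test differed in sign for the receptor, cholesterol efflux, solute carrier and cell cycle lists, which were not called.

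Markers of other cell types were examined for counts. Of 36 genes typical of T cells or of Jurkat cells, 4 passed the expression filter, too few for a list test, and the highest count of any of the 36 in a library was 406. Cd5, a T cell surface protein, rose at 180 min by 1.98 (SE 0.60), from 0.426 to 1.70 CPM, here the counts summed over the 4 libraries of a group divided by their unscaled totals. The transcription factor Tal1 rose by 0.76 (SE 0.19) at 180 min, the co-stimulatory receptor Cd28 fell by 0.37 (SE 0.13) at 90 min, a call lost without library 3 or 4 of macrophages alone or 1 or 4 of 90 min, with voom and with libraries thinned (-0.37 to -0.31, adjusted p from 0.0132 to 0.108 over all alternatives), and Lat, with 0.284 CPM alone and 0.557 CPM at 180 min, was not called. Dendritic cell markers passed the filter in 3 of 13 cases, of which Cd83, also a general activation marker, rose by 1.02 (SE 0.14) at 180 min and Itgax and Batf3 were not called against macrophages alone. Progenitor markers passed in 3 of 11 cases, with up to 9194 counts of a gene in a library, that gene being Cdk6. Those that did not pass, among them Cd34 and Kit, had at most 9 counts summed over a group. Of the 3 that passed, Hoxb8 fell by 0.37 (SE 0.099) and Cdk6 fell by 0.25 (SE 0.049) at 180 min, and Sox4, at 0.456 CPM alone, 1.02 CPM at 45 min and 0.571 CPM at 180 min, was not called. Of 18 neutrophil markers 5 passed, with up to 3732 counts. B cell markers passed in 2 of 8 and erythroid or mast cell markers in 0 of 11, the last with 37 counts over all 16 libraries. The genes of these cell types named here were chosen after their values were seen. The table holds mouse genes, and how reads from the human cells were handled is not given in the sources used here.

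Calls at the 3 times were compared, all against the same 4 libraries of macrophages alone. Of the genes called at both 90 and 180 min, 2206 moved the same way and 32 opposite ways. At both 45 and 90 min the numbers were 519 and 138, with Fos, Dusp1 and Btg2 among those that rose at 45 min and fell at 90 min. At both 45 and 180 min they were 583 and 224, the latter including Egr1. Independent lists of these sizes would share 237 higher and 226 lower genes at 90 and 180 min, 73.7 and 86.3 at 45 and 90 min, and 100.2 and 138 at 45 and 180 min. Unchanged groups simulated against the same controls shared 0 calls in the mean of 20 data sets. No gene was changed in these data sets, so that count cannot show how much shared controls add to the overlap of genes that did change. With the controls split 2 and 2, so that the times shared none, the mean overlap over 6 splits was 1297 genes for 90 and 180 min, 252 for 45 and 90 min and 305 for 45 and 180 min. Across 10701 genes, which are not independent replicates, log2 fold changes at 90 and 180 min correlated at r = 0.758, against 0.475 in the simulations. Those at 45 min correlated with those at 90 and 180 min at r = 0.282 and 0.208, against 0.492 and 0.494. The simulated values are those of groups in which no gene changed. With the controls split 2 and 2 the mean r was 0.651 for 90 and 180 min, 0.166 for 45 and 90 min and 0.118 for 45 and 180 min. The covariance was 0.0759 for 90 and 180 min, 0.0177 for 45 and 90 min and 0.0159 for 45 and 180 min, where shared controls alone gave 0.00772, 0.00769 and 0.00767.

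**Figure D3:**
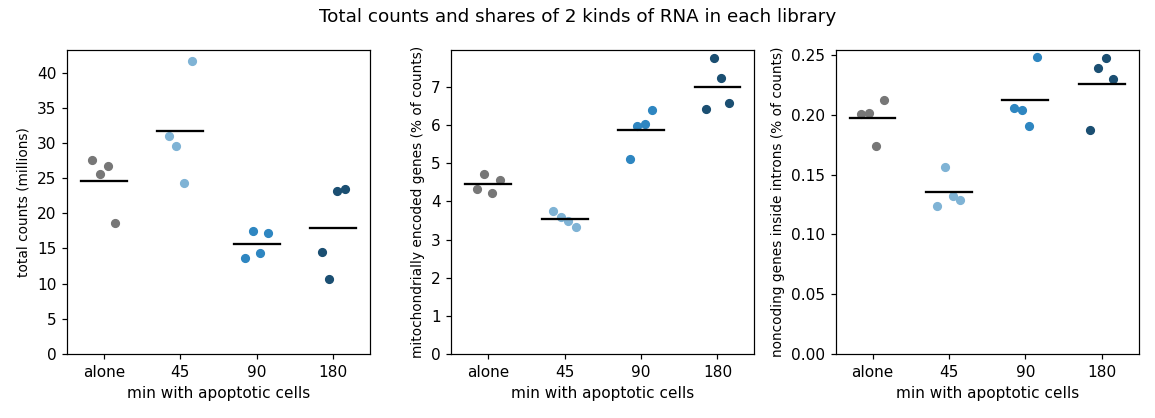
Total counts in M, the percentage of counts from mitochondrially encoded genes and the percentage from noncoding genes inside introns (vertical axes), for each library of macrophages alone and at 45, 90 and 180 min with apoptotic cells. Each point is a library and the line is the mean of the 4, which for the mitochondrial share was 4.45% alone and 7.0% at 180 min.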

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

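The tests of ribosomal RNA depletion, of human RNA, of the handling of macrophages kept alone, of gene length and GC content and of depth were chosen only after the patterns they bear on were seen. Chance puts a library far from the other 3 in about 1 of 20 groups. By Dixon's ratio of the gap to the range, 18 of 512 groups of 4 held such a library, where 25.6 were expected by chance. In macrophages alone these were library 1 for Il10 (low, ratio 0.839) and Lrp1 (high, 0.837) and library 3 for Odc1 (high, 0.913) and Smad6 (high, 0.849). At 45 min library 2 was high for Cdk6 (0.849). At 90 min library 1 was low for Ccl3 (0.976) and Pgap1 (0.846) and high for Cish (0.852), library 2 was high for Cd5 (0.943) and library 4 low for Axl (0.929). At 180 min library 1 was low for Cables1 (0.890) and high for Mx1 (0.909), and library 2 was low for Csrnp1 (0.888) and Egr2 (0.862) and high for Il10 (0.841) and Mir17hg (0.911). Library 4 at 180 min was low for Abhd18 (0.904) and Zfp467 (0.919).

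Several genes changed in opposite directions at different times against macrophages alone, and the difference between the times was tested directly by edgeR. Most were higher at 45 min and lower at a later time. From 45 to 90 and from 45 to 180 min the log2 differences were -2.15 and -1.92 for Btg2, -1.59 and -2.30 for Chac1, -1.39 and -1.88 for Dusp1, -1.59 and -1.12 for Fos, -1.71 and -1.5 for Ier2, and -0.52 and -1.22 for Nfkbiz. From 45 to 180 min they were -2.66 for Egr1, -1.11 for Ccl4, -1.08 for Csrnp1 and -1.54 for Cxcl2, and from 90 to 180 min -1.26 for Egr1 and -0.88 for Ccl4. In the other direction, Klf2 differed by 1.26 from 90 to 180 min, Lrp1 by 0.67 from 45 to 180 min, and Klhl42 by 1.19 and 1.53 from 45 to 90 and to 180 min.

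Among interferon response genes Cmpk2 differed by -0.28 and -1.18 and Mx1 by -0.28 and -1.14 from 45 to 90 and to 180 min, and Ifit3b by -1.11 from 45 to 180 min. A different handling of the macrophages kept alone is argued against as the whole cause of the fall at 180 min, because 28 of 29 members also fell from 90 to 180 min, where those libraries do not enter the difference. Lower depth is argued against because 27 members fell with all libraries thinned to the smallest total (median -0.53), and gene length and GC content because 27 fell with that trend removed (median -0.51). An effect of exposure to apoptotic cells and an effect of time in culture stay open, since the labels give no group kept alone for each time.

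Among mitochondrial genes mt-Cytb differed by 0.92 and 1.37 and mt-Rnr2 by 0.72 and 0.94 from 45 to 90 and to 180 min. A difference in ribosomal RNA depletion is argued against as the whole cause, because the 7 mitochondrial messenger RNAs that passed the expression filter rose by a median of 1.01 at 180 min (0.88 to 1.37) against 0.63 for the ribosomal RNAs. Gene length and GC content are argued against because the list median was 0.90 with that trend removed and 0.91 before, with a lowest member at 0.58. RNA of the human cells stays open: the list median was -0.31 at 45 min, when those cells were also present, but their mitochondrial RNA could be taken up or released later, and its reads may map to mouse genes. An effect of exposure and an effect of time in culture on the macrophages were not tested and also stay open.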

How the results depend on the processing

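The tests with libraries thinned to the smallest total, with a trend on gene length and GC content removed and on coding genes alone were chosen only after the data were seen. No paired analysis was possible because the labels number the samples but the columns of the table carry no replicate numbers, so the fits with a replicate block were not run. An added condition of an absolute log2 fold change of at least 1 left 223 genes at 45 min, 336 at 90 min and 502 at 180 min against macrophages alone, 519 from 45 to 90 min, 98 from 90 to 180 min and 765 from 45 to 180 min, fewer by construction. Genes called at both times under that condition numbered 16 for 45 and 90 min, 15 for 45 and 180 min and 170 for 90 and 180 min. With the controls split in 2 and 2 they numbered 252, 305 and 1297, where fewer controls entered each fit. With the length and GC trend removed 893 genes were called at 45 min, 432 higher and 461 lower, in place of 1529, and the cause was not tested. Every other count of genes under DESeq2, its scaling, voom, either filter, 2 groups alone, mitochondrial genes removed, thinning, length and GC correction or coding genes alone was within 1.5 times the reported one. Where rises and falls were near even, some of these alternatives changed the larger side: 90 min with mitochondrial genes removed had 1523 higher and 1524 lower, 180 min with the stricter filter 2254 and 2146 and with its 2 groups alone 2247 and 2228, and with the length and GC trend removed 2431 and 2181. From 45 to 90 min no filter gave 1777 and 1998 and 2 groups alone 1913 and 1995, and from 45 to 180 min 2310 and 2539 and 2523 and 2615. A test of coding genes alone also changed the larger side, with 649 higher and 642 lower at 45 min in place of 664 and 865. It did so too at 180 min (2074 and 1956) and from 45 to 180 min (2172 and 2212). Without 1 library the counts ran from 1079 to 1714 at 45 min, 2369 to 3147 at 90 min, 3781 to 4534 at 180 min, 3335 to 4214 from 45 to 90 min, 1384 to 1597 from 90 to 180 min, 4495 to 5310 from 45 to 180 min and 5823 to 6524 for any time.

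With an estimated correlation 4, 1, 1, 2, 1 and 1 lists were called in the 6 comparisons, in the order above, in place of 16, 17, 8, 12, 6 and 10. Fry, which does not compare a list with other genes, called 17 at 180 min, 19 from 45 to 90 min, 11 from 90 to 180 min and 16 from 45 to 180 min. The cause of these differences was not tested. List tests were also not run on coding genes alone. Without 1 library the lists called ran from 15 to 16, 15 to 17, 7 to 10, 11 to 13, 4 to 6 and 10 to 10. Of the 69 list calls, leaving out a library kept 1073 and ended 31 of the tests rerun. Fry ended 2, thinning 4 and the length and GC correction 5. They include the ribosomal protein call at 90 min, lost by fry (adjusted p = 0.13, and 0.00359 to 0.512 over all alternatives). By a limit of 0.05 of the splits, chance assignment of libraries to groups is excluded for the counts of genes: of 35 splits 1, the real one, gave as many at 45 min (1529, highest other 0), 90 min (2986, 1), 180 min (4404, 0), from 45 to 90 min (3984, 2), from 90 to 180 min (1618, 7) and from 45 to 180 min (5152, 7), as did 1 of 100 for any time (6322, 480). A share of 1 of 35 is the smallest these splits can give. They cannot exclude a difference in culture or handling between groups. For counts of lists chance is not safely excluded. At 45 min 1 of 35 splits, the real one, gave as many (16 lists, highest other 15) and at 90 min likewise (17 and 16), but the margin was 1 list. With mitochondrial genes removed the real counts were 15 and 16, because their own list was then gone and no other call was lost. The splits were not rerun without that list, so these counts cannot be set against them. Chance is not excluded at 180 min (4 of 35, 8 and 10), from 45 to 90 min (5, 12 and 13), from 90 to 180 min (4, 6 and 7) or from 45 to 180 min (7, 10 and 12).

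The 201 gene values given in the text kept their direction in all 5410 checks under these alternatives. In 127 a call was lost: 95 under an absolute log2 fold change of at least 1, 23 with a library left out, 5 with thinning, 2 with no filter, 1 with voom and 1 with the length and GC correction. The kept directions are partly built in. The condition on the log2 fold change refits nothing, and some left-out libraries belong to neither group compared. Many of the genes were also named for a large change or a small p in these same data. The median of all genes was at most 0.0241 from 0 under each scaling run. Thinning to the smallest total, 10.7 M counts, left 1206 genes called in place of 1529 at 45 min, 2610 in place of 2986 at 90 min and 3949 in place of 4404 at 180 min. In data simulated at the real depths, depth was not varied and only 200 genes were changed. There 70.1%, 67.2% and 61.2% of genes changed 1.5-fold were recovered at these times.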

Other observations

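The tests of nuclear RNA, of genomic DNA and of gene length and GC content and the 2 lists of cyclic AMP and TGF-beta genes were chosen only after the results they bear on were seen, and so were the genes Neat1, Malat1, Tug1, Smad7 and Pmepa1. Several long noncoding RNAs were higher at 90 and 180 min than in macrophages alone. By edgeR's quasi-likelihood test Neat1, the RNA that builds paraspeckles, rose by 0.41 (SE 0.072) at 45 min, by 1.25 (SE 0.073) at 90 min and by 1.32 (SE 0.073, adjusted p = 5.89e-23) at 180 min. Malat1, an abundant RNA of nuclear speckles, rose by 0.79 (SE 0.055) at 90 min and by 0.67 (SE 0.055, adjusted p = 1.3e-15) at 180 min. It alone held 1.08 ± 0.0905% of counts in macrophages alone, 1.22 ± 0.145% at 45 min, 1.85 ± 0.187% at 90 min and 1.74 ± 0.213% at 180 min (SD, n = 4 each). Tug1 rose by 0.57 (SE 0.053) at 90 min and by 0.59 (SE 0.053, adjusted p = 3.01e-14) at 180 min. Human reads that resemble these genes could be among their counts, which was not tested. At 180 min 63 of 379 long intergenic noncoding genes rose and 11 fell, as did 54 and 9 of 381 antisense and 44 and 6 of 232 processed transcripts. Their medians were 0.32, 0.34 and 0.36, against -0.01 for coding genes. From 90 to 180 min 3 long intergenic noncoding genes rose and 18 fell, with 2 and 11 for antisense and 2 and 11 for processed transcripts.

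Beside Smad6, 2 other genes that restrain TGF-beta or BMP signalling were higher at 180 min. Smad7 rose by 0.41 (SE 0.11) at 45 min, by 0.93 (SE 0.11) at 90 min and by 1.80 (SE 0.10, adjusted p = 4.17e-22) at 180 min, and Pmepa1 rose by 0.59 (SE 0.13) at 90 min and by 1.62 (SE 0.12, adjusted p = 5.62e-17) at 180 min. A hypothesis is that these genes were part of a wider rise of TGF-beta and BMP target genes. Of 27 tested genes of a list drawn up for this question, 15 rose and 3 fell at 180 min (camera p = 7.06e-08, and adjusted p = 0.000796 with an estimated correlation), but the list was made after its leading genes had been seen. Among the 12 tested members whose values had not been seen, 5 rose and 2 fell (camera p = 0.046, and adjusted p = 0.133 with an estimated correlation), so the hypothesis may hold and stays open. At 45 and 90 min these 12 gave a camera p of 0.259 and 0.693, and camera p-values in this part, unlike those with an estimated correlation, are not adjusted.

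The rises of Adora2b and Rapgef3 raised the hypothesis that genes responsive to cyclic AMP rose as a group. Of 28 tested genes of such a list 12 rose and 7 fell at 180 min (camera p = 0.185, and adjusted p = 0.214 with an estimated correlation). At 45 and 90 min the list gave a camera p of 4.54e-11 and 0.0404, and an adjusted p of 3.2e-05 and 0.079 with an estimated correlation, but 14 of its 28 genes are also in the lists fixed in advance. Among the 8 members whose values had not been seen, 3 rose and 2 fell at 180 min. Camera of limma, which sets them against all other genes tested, gave an unadjusted p of 0.892 at 180 min, and 0.391 and 0.989 at 45 and 90 min. That is no evidence for a rise as a group and, with so few genes, does not exclude one.

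Of 1004 noncoding genes inside introns 213 fell and 4 rose at 45 min against macrophages alone, with a median of -0.71, and 296 were higher at 90 than at 45 min by the test. With the trend on gene length and GC content removed their median was -0.72 and 188 were called lower, which argues against that trend as the whole cause. Less genomic DNA in the 45 min libraries stays open. The summed CPM of 1961 odour and pheromone receptor genes, all below the expression filter, differed by a log2 ratio of 0.00376 (SE 0.18) between 45 min and macrophages alone, but the lowest sum in a library was 39 counts. Loss of nuclear RNA also stays open: the median of Malat1, Neat1 and Tug1 at 45 min was 0.18, but other nuclear RNA could be lost while these are kept, and a lower amount of unspliced RNA in the cells was not tested, so these cannot be told apart.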
